A study of Arabidopsis thaliana with 12 samples.

How the data were processed

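Arabidopsis thaliana plants of the Landsberg ecotype were profiled on single-channel arrays after 48 hours either in red light at 200 µE or in white light at 20 µE, with 6 arrays per light condition. Light colour and light level changed together between the groups, so the comparison cannot separate them. The labels do not say which plants, RNA extracts or membranes lie behind each array. P-values therefore measure the spread between these arrays, part of which may be technical.

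The deposited table holds 1 linear intensity value per feature and array for 3439 features. What the authors did to make these values (background correction, the floor at 0 and the scaling) is not given in the sources used here. The values run from 0 to 100, none is negative, and the highest value of an array is 100 (to 3 decimals) on 7 of the 12 arrays. Array medians ranged from 0.233 to 0.471, a ratio of 2.02, so the deposited intensity values were not on a common median. Exact zeros made up 11.4% to 17% of the features of an array, and 173 features were listed at 0 on all 12 arrays. Signal over local background is not known, and the number of arrays limits the precision.

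Feature names come from GEO's annotation of the array platform, with symbols updated through the Entrez gene identifier in the RefSeq table of assembly TAIR10.1. Of the 3439 features, 692 are listed with 1 gene, 870 with several genes and 1877 are not listed, which leaves them unnamed here. Of the 692, 690 matched the RefSeq table. Features with several genes or none are given by their number on the array. The annotation is old and its probe sequences were not used here. Close paralogs such as the chlorophyll a/b-binding genes could share signal on an array of this kind.

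From the deposited values, intensities were quantile-normalized across the 12 arrays because the ratio of the array medians exceeded a limit of 1.25 that had been set in advance. The values were then transformed as log2(intensity + 0.054), where 0.054 is percentile 5 of the positive values. The log2 differences of dim features depend on this pseudocount and understate their fold change. Features of the same gene were averaged, which left 3438 rows. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), and adjusted p values below are from this test unless another is named.

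Within each group, arrays 1 and 2, 3 and 4, and 5 and 6 proved to be near-duplicates. Their rank correlations were 0.91 to 0.989, against 0.641 to 0.821 for other arrays of the same group. The closest array within the group was the consecutive number for 12 of 12 arrays. The design written before the data were examined entered the 12 arrays as separate samples, with averaging of these pairs as an alternative. Because near-duplicates are counted as 1 sample, the reported fit uses the means of the pairs, 3 against 3 with 4 residual degrees of freedom. This choice was made after the data were examined, it departs from the design written in advance, and the fit of 12 separate arrays is reported as an alternative. Means ± SD below are over 3 pair means.

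The numbers are shared by both groups, so the pairing was checked on deviations from the group means. These deviations correlated at 0.171 to 0.409 between same-numbered arrays of the 2 groups, and at 0.125, 0.466 and 0.376 between same-numbered pair means. All exceeded the limit of 0.1, so the numbers were taken to pair the samples. The pairing comes from this check, which is no test, and not from a statement in the labels. It is weakest for number 1, as red array 1 had a rank correlation of 0.733 with white array 5 and 0.67 with white array 1. A fit with the pair number as a block is given beside the calls and counts it changes. SEs, and adjusted p values without a named fit, leave this pairing out.

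Genes were chosen by a rule written before the data were examined. Part (a) took the 6 largest positive and 6 largest negative differences among features past an adjusted p of 0.05 in the 12-array fit whose 6 values in 1 group all lay above the 6 of the other, with a mean level above the lower quartile. Part (b) took the 2 smallest p values in each gene list with at least 3 measured members. Part (a) was repeated among features with 1 gene, and all measured list members are given. Both of these were added after the data were examined.

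A total of 20 gene lists with 339 genes was fixed in advance, covering photosynthesis, chloroplast metabolism, stress, import and signalling, with root plastid isoforms and senescence genes as markers of other tissue or tissue state. Only 16 of these genes are on features named with 1 gene, 12 lists have no measured member, and 1 list (plastid ribosomal proteins) has at least 3. The root and senescence lists are among the 12, so these markers could not be read. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. In addition, 3 lists were put together after the data were examined, namely the pooled photosynthesis genes, a plastid NDH list and a GH9B list.

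Alternatives covered the deposited scale, median scaling, the pseudocount multiplied or divided by 4, removal of the dimmest 25% of features or of features at 0 throughout a group, the replicate block, the treatment of near-duplicates, array weights, a trended robust prior, an exact permutation test over 924 assignments of the 12 arrays, and leaving out each array or pair. The random block for near-duplicates uses 1 within-pair correlation of 0.85 for all features and takes its residual degrees of freedom from the 12 arrays. Its p values can therefore be too small for a contrast of 3 against 3 samples. The fit of pair means was tested on simulated data with 200 changed rows of 3438 and the spread of the pair means. It recovered 5.18% of log2 changes of 1, 30.8% of changes of 2 and 59.4% of changes of 3, with on average 0.55, 5.85 and 8.6 false calls. The design therefore detects mainly large changes.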

Results

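Transcript levels of Arabidopsis plants kept for 48 hours in red light at 200 µE were compared with those of plants kept for 48 hours in white light at 20 µE. Each condition was represented by 6 arrays carrying 3439 features. On the deposited scale the median intensity was 0.417, 0.425, 0.455, 0.471, 0.237 and 0.233 on red arrays 1 to 6. It was 0.237, 0.238, 0.288, 0.289, 0.276 and 0.271 on white arrays 1 to 6. The share of features listed at 0 was 15.5% ± 1.38 in red and 12.9% ± 1.11 in white light (SD, n = 3 pair means each). Every red pair lay above every white pair in this share, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 can give.

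Consecutive array numbers of a group gave nearly the same profile. The median rank correlation was 0.956 between these near-duplicates and 0.722 between other arrays of the same group. The SD of the log2 difference between 2 arrays had a median of 0.465 for near-duplicates and 1.13 for other arrays of the group. Each group was therefore treated as 3 samples. The profiles did not sort by light alone. Red array 5 had a rank correlation of 0.765 with white array 5, higher than its 0.693 with red array 1 and 0.66 with red array 3. White array 5 correlated at 0.733 with red array 1, 0.758 with white array 3 and 0.647 with white array 1.

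**Figure D1:**
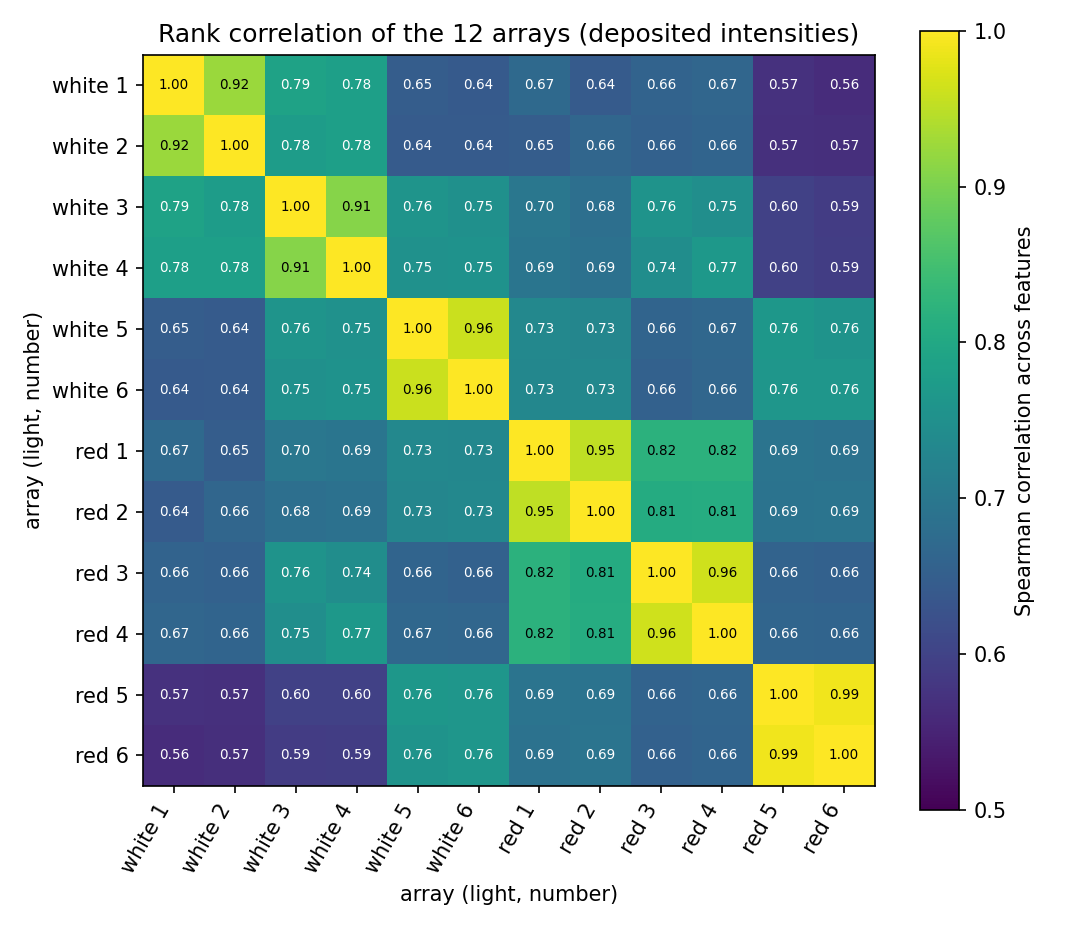
Spearman rank correlation across all features between each 2 of the 12 arrays (rows and columns, white arrays first), on the deposited intensities, with the value written in each cell. The 6 near-duplicate pairs range from 0.91 to 0.989, and other arrays of the same group from 0.641 to 0.821.

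The gene AT3G54550 rose in red light, from a normalized intensity of 0.563 ± 0.0291 to 1.31 ± 0.0834 (SD, n = 3), a 2.21-fold increase on the log2(intensity + 0.054) scale (adjusted p = 0.0471). The other 3 features past the threshold fell and could not be tied to 1 gene, as feature 628 is listed with 2 genes and features 4514 and 3724 with none. Feature 628 fell from 1.46 ± 0.0803 to 0.429 ± 0.0435 and feature 4514 from 0.305 ± 0.037 to 0.065 ± 0.00483 (SD, n = 3), 3.13-fold and 3.01-fold lower on the same scale (adjusted p = 0.0346 for both). Feature 3724 had an intensity of 0.147 ± 0.022 in white light (SD, n = 3) and was listed at 0 on all 6 red arrays (adjusted p = 0.0346). In each of the 4, the 6 red arrays did not overlap with the 6 white arrays. All 3 pairs of same-numbered samples then differ in the same direction by necessity, which is no separate support. These calls did not hold with the pair number as a block, where each of the 4 had an adjusted p = 0.144 at an unchanged difference and 2 residual degrees of freedom. The log2 difference of feature 4514, -1.59, was -0.89 with the pseudocount multiplied by 4 (adjusted p = 0.0683) and -2.02 with it divided by 4, and that of feature 3724, -1.89, was -0.75 (adjusted p = 0.0683) and -3.56. With the near-duplicates as a random block the 3 features that fell passed, and AT3G54550 had an adjusted p = 0.462. The log2 difference of that gene, 1.14, was 0.89 without white array 5 and 1.37 without white array 6. These near-duplicates thus differed for this gene, which the SD over pair means does not show. On the deposited scale AT3G54550 differed by 1.72. It passed the threshold in 11 of 32 alternatives.

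These 4 were the features of 3438 past an adjusted p of 0.05, with 1 higher and 3 lower in red light. At an unadjusted p under 0.05 there were 475 features, 239 higher and 236 lower, where 172 would be expected with no effect and independent features. The pair means of the 2 groups did not overlap for 601 features (17.5%), where chance gives 10%. The difference between red and white had the same sign in all 3 same-numbered pairs for 37.8% of features, where independent signs would give 25%. Across features, which are not independent replicates, the red minus white differences of the pairs correlated at 0.5 between pairs 1 and 2, 0.382 between pairs 2 and 3, and 0.109 between pairs 1 and 3.

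With the pair number as a block, 0 features passed the adjusted threshold in limma, with 645 at an unadjusted p under 0.05. Without arrays 5 and 6 of both groups, 0 passed and 626 had an unadjusted p under 0.05. The fit of 12 separate arrays called 564 features, 274 higher and 290 lower, and its p values are too small because near-duplicates enter it as independent samples.

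Among nuclear photosynthesis genes, none of the 6 measured members passed the threshold, and their differences went both ways. PSBW, a small subunit of photosystem II, was among the brightest features and had an intensity of 52 ± 22.4 in red and 16.1 ± 2.27 in white light (SD, n = 3). Its log2 difference was 1.58 ± 0.41 (SE, adjusted p = 0.216), positive in all 3 pairs. With the near-duplicates as a random block PSBW passed the threshold (adjusted p = 0.0418), the only one of the fixed-list genes to do so. The p values of that fit can be too small. PSBY, another photosystem II protein, differed by 0.74 ± 0.28 (SE), with 2.31 ± 0.602 in red and 1.35 ± 0.323 in white light (SD, n = 3). PSAN, a lumenal subunit of photosystem I, differed by -0.70 ± 0.27 (SE), with 2.11 ± 0.195 in red and 3.58 ± 1.15 in white light (SD, n = 3). The antenna gene LHCB1.5, which encodes a chlorophyll a/b-binding protein, had 7.74 ± 2.5 in red and 15.8 ± 9.4 in white light (SD, n = 3), with pair differences of 0.23, -1.60 and -1.03. The fitted difference of LHCB1.5, -0.80, ranged from -1.51 without white arrays 1 and 2 to -0.48 without white 3 and 4 and -0.40 without white 5 and 6. On the deposited scale LHCB1.5, PSAN and PSBY differed by -0.38, -0.13 and 1.27, and with array weights LHCB1.5 and PSAN by -1.38 and -0.32. The Calvin cycle gene PRK (phosphoribulokinase) had 0.707 ± 0.0729 and 0.749 ± 0.25. SBPASE, encoding another Calvin cycle enzyme, was listed at 0 on all 12 arrays, which says nothing on its expression. The adjusted p values of PSBY, PSAN, LHCB1.5 and PRK were 0.361, 0.372, 0.709 and 1. Adjusted over the list alone, 0 of the 6 passed, with a smallest value of 0.079 for PSBW. As a pooled list, assembled after the data were examined from lists fixed before, these genes did not stand apart from the other features (camera p = 0.595, and p = 0.615 with an estimated correlation). The list's median log2 difference was -0.02 and its mean 0.13, which differ in sign. The mean was 0.58 on the deposited scale, 0.23 with median scaling, 0.03 with array weights and 0.06 to 0.24 without 1 near-duplicate pair. By fry, a rotation test, the list missed the threshold for a shift one way (adjusted p = 0.376 over the 4 lists tested). For differences in either direction it fell below 0.05 only before adjustment (adjusted p = 0.0796).

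The plastid ribosomal proteins, the translation machinery of the chloroplast, were the only list fixed in advance with enough members for a test. None of the 6 passed the threshold over all features or adjusted over the list alone. PRPL34 (AT1G29070) had a normalized intensity of 0.132 ± 0.119 in red and 0.832 ± 0.531 in white light (SD, n = 3), with pair differences of -2.22, -2.23 and -2.50 on the log2 scale (adjusted p = 0.373). It was listed at 0 on 2 of 6 red arrays. Its fitted difference, -2.32, was -1.49 without red arrays 5 and 6 and -1.50 with the pseudocount multiplied by 4. PRPL29 (AT5G65220) had 1.8 ± 0.746 in red and 4.25 ± 1.76 in white light (SD, n = 3), a log2 difference of -1.21 ± 0.42 (SE, adjusted p = 0.326) that was negative in all 3 pairs and -0.50 on the deposited scale. PRPL5, PRPL17 and PRPS10 had log2 differences of 0.40, 0.39 and 0.06, and PRPS6 was at 0 on 5 white and 6 red arrays. PRPL5 and PRPL17 differed by 0.92 and 0.80 on the deposited scale, by 0.80 and 0.22 without white arrays 1 and 2, and by 0.14 and 0.60 without arrays 5 and 6 of both groups. Without white arrays 5 and 6, PRPL5 differed by -0.0141. The mean difference of the list was -0.46 and its median -0.01, as 3 members lay above and 3 below 0. The list did not stand apart from other features (camera p = 0.549, and p = 0.573 with an estimated correlation). The fry test, which asks only whether the members move one way on balance, fell below 0.05 before adjustment but not over the 4 lists tested (adjusted p = 0.155). For differences in either direction it gave an adjusted p = 0.109.

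In chlorophyll synthesis, CHLP (AT1G74470, geranylgeranyl reductase) had intensities of 3 ± 0.246 in red and 3.47 ± 0.198 in white light (SD, n = 3), with pair differences of -0.20, -0.25 and -0.18 on the log2 scale (adjusted p = 0.45). Its fitted difference of -0.21 was -0.07 with median scaling and -0.14 without red array 4. On the deposited scale its difference was 0.35, and those of PRK and CHLM also turned positive there. CHLM, the magnesium protoporphyrin IX methyltransferase, had 0.496 ± 0.225 and 0.516 ± 0.137. FATB, an acyl-ACP thioesterase of fatty acid synthesis, had 0.174 ± 0.106 in red and 0.0661 ± 0.0338 in white light (SD, n = 3), with an adjusted p of 0.501. Its log2 difference of 0.84 was 0.51 with median scaling or without red arrays 5 and 6, and 0.43 with the pseudocount multiplied by 4. The peroxiredoxin gene PRXIIE, the only measured member of the antioxidant list, had 0.291 ± 0.118 and 0.292 ± 0.124. In all, 0 of the 16 measured genes of the fixed lists passed the threshold in the fit of pair means. Of their differences, 7 lay above 0 and 8 below, with SBPASE at 0 throughout. The fit of 12 separate arrays, whose p values are too small, called 5 of the 16 (PRPL29, PRPL34, PSAN, PSBY and PSBW), against 564 of all 3438 features. With the replicate block that fit called 6 (PRPL34, FATB, PSAN, PSBY, PSBW and CHLP), against 826.

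**Figure D2:**
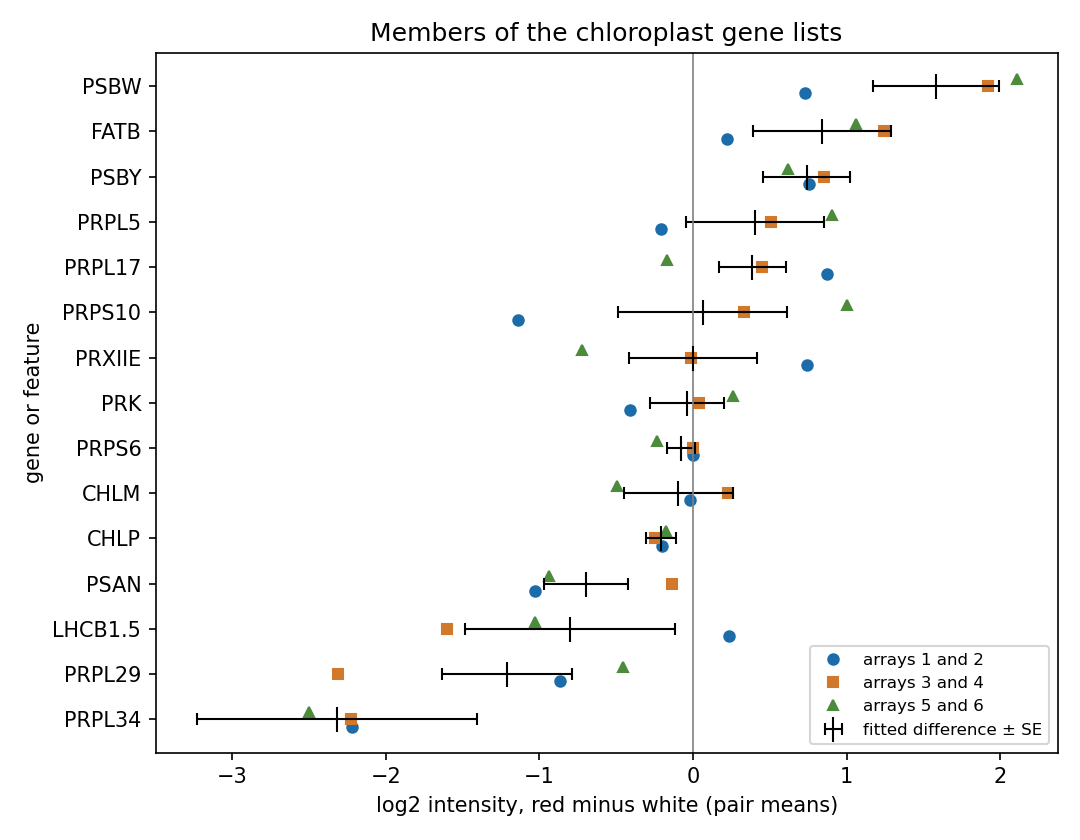
Red minus white difference in log2 intensity (x axis) for the measured members of the gene lists fixed in advance (y axis), without SBPASE, which was listed at 0. Symbols are the 3 same-numbered pair means and black bars the fitted difference ± SE. PSBW lies highest at 1.58 and PRPL34 lowest at -2.32, and no member passed the adjusted threshold in the fit of pair means.

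The largest differences among features that separated all 6 red from all 6 white arrays were mostly on unnamed features. None of the 12 chosen by size passed the threshold in the fit of pair means, where their adjusted p ranged from 0.0775 to 0.307. With the near-duplicates as a random block 9 of the 12 passed, with array weights 4, on the deposited scale 3 and with the pair number as a block 0. The 12 were chosen because they passed in the 12-array fit, so passing in another fit of these arrays is no separate support. The 6 with positive differences ranged from 2.99 to 4.48 on the log2 scale. Feature 3452 had 6.05 ± 1.75 in red and 0.652 ± 0.142 in white light (SD, n = 3), and AT4G13680 had 1.57 ± 0.614 and 0.0182 ± 0.0272 (adjusted p = 0.0786). AT4G13680 was listed at 0 on 4 of the 6 white arrays, so its log2 difference of 4.48 depends on the pseudocount and was 2.85 with it multiplied by 4. With that pseudocount feature 3769 differed by 1.71 and feature 134 by -1.58, against 3.03 and -2.47. AT4G13680 passed the threshold without the dimmest features, without features at 0 throughout a group and without white array 3 (adjusted p = 0.0155, 0.0208 and 0.0427). The 6 negative differences ranged from -4.14 to -2.47, led by feature 3533 with 0.535 ± 0.774 in red and 4.83 ± 1.81 in white light (SD, n = 3). In 5 of these 6 the difference was largest in size in pair 1, and in all 6 it was smallest in pair 3. Features 3533, 3819 and 134 were each listed at 0 on 2 red arrays, those of pair 1, so their pair 1 differences depend on the pseudocount.

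Among features with a gene name, the same rule gave 12 genes, and again none passed in the fit of pair means. With the near-duplicates as a random block 5 of them passed, namely AT4G13680, AT1G78620, AT2G46050, AT1G02020 and AT1G63720, and with the pair number as a block 0. In that block fit AT4G13680, AT4G17070, AT2G46220 and AT2G46050 had an adjusted p = 0.144, as had the 4 called features, and the others of the 12 a larger one. These genes, too, were chosen from the 12-array fit. With array weights 5 passed, among them AT4G17070 and AT1G22700. AT1G22700, also known as PYG7 and required for photosystem I accumulation, had 1.18 ± 0.434 in red and 0.226 ± 0.15 in white light (SD, n = 3). AT1G78620, also known as VTE6 and acting in phytol recycling for tocopherol synthesis, had 1.63 ± 0.804 and 0.278 ± 0.0581. Their adjusted p values were 0.183 and 0.178. AT4G17070 was among the brighter features, with 18 ± 7.77 in red and 3.2 ± 1.59 in white light (SD, n = 3) and log2 pair differences of 2.35, 2.73 and 2.43. AT2G46220 and AT2G46050 had log2 differences of 2.35 and 2.06. On the other side, AT1G63720 had 0.227 ± 0.0347 in red and 0.816 ± 0.152 in white light (SD, n = 3), with pair differences of -1.32, -1.65 and -1.90 (adjusted p = 0.0791). AT5G05330, AT1G02020, AT5G59060, AT2G04360 and the glycosyl hydrolase gene GH9B12 had log2 differences of -2.29, -1.93, -1.85, -1.71 and -1.70. That of AT5G05330 was -1.35 without red arrays 5 and 6, -1.47 without arrays 5 and 6 of both groups and -1.47 with the pseudocount multiplied by 4. With that pseudocount AT2G04360 differed by -1.06, and without white arrays 1 and 2 GH9B12 by -1.10.

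**Figure D3:**
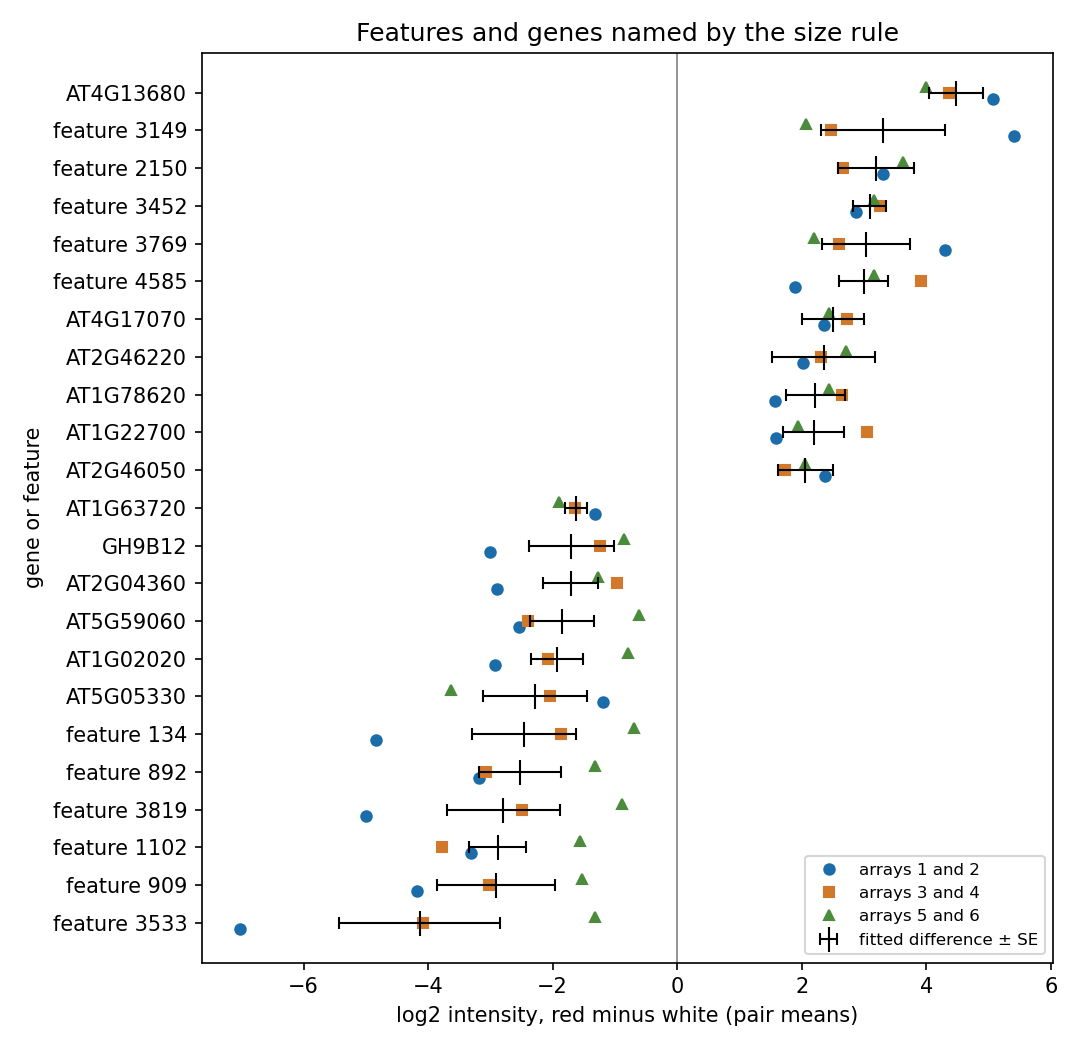
Red minus white difference in log2 intensity (x axis) for the features and genes chosen by size (y axis), with symbols for the 3 same-numbered pair means and black bars for the fitted difference ± SE. All 3 pairs of each item lie on the same side of 0, by the rule that chose them, and feature 3533 ranges from -7.01 to -1.32. The -7.01 belongs to pair 1, where both red arrays were listed at 0, so it depends on the pseudocount.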

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

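The count of 4 features past the adjusted threshold depended on the processing. It was 27 on the deposited scale (23 higher, 4 lower in red light), 1 with arrays scaled to the same median, 2 with the pseudocount multiplied by 4, 3 with it divided by 4, 1 without the dimmest 25% of features and 1 with a trended and robust prior. With the near-duplicates as a random block it was 105, with array weights 104, and with an exact permutation test of each feature over the 12 arrays 473. The p values of the random block can be too small, and the permutation test takes near-duplicates as independent. With the replicate block, which takes the shared numbers as pairs, the count was 0. Alternatives chosen after seeing the data gave 1 without features at 0 on all arrays of a group and 0 without arrays 5 and 6 of both groups. The fit written before the data were examined, with 12 arrays as separate samples, gave 564, and 826 with the replicate block. Leaving out 1 array at a time gave 0 to 5 features (0 without white array 1, 2 without white array 5). Leaving out 1 near-duplicate pair, also chosen after seeing the data, gave 0 to 2, with 0 in each case but white arrays 5 and 6. Of the 32 alternatives, AT3G54550 passed in 11, feature 628 in 18, feature 4514 in 17 of the 31 that tested it, and feature 3724 in 20 of 30. Most of these passes came from fits that drop 1 array but keep its near-duplicate, or that take the 12 arrays as separate samples. None of the 4 passed with the pair number as a block. Those still tested without the dimmest 25% of features, or without features at 0 on all arrays of a group, did not pass either. Without a near-duplicate pair only feature 3724 passed, in the fit without white arrays 5 and 6. The directions of the 4 did not change. The call without the dimmest 25%, and that without features at 0 on all arrays of a group, was a different gene, AT4G13680. The plastid ribosomal list had a mean difference of -0.459, and its camera test missed the threshold under each alternative run. Only the fry rotation test fell below 0.05, with the same mean of -0.459, and that only before adjustment over 4 lists (adjusted p = 0.155). On the deposited scale the mean was -0.03. Leaving out arrays or pairs moved the mean from -0.624 to -0.35. The list was not tested with the random block. Near-zero differences turned sign. PRK gave 0.58 on the deposited scale, 0.18 with median scaling and 0.12 with array weights. PRXIIE gave -0.14 with median scaling, -0.0011 with the pseudocount multiplied by 4 and -0.14 with array weights. CHLM and CHLP gave 0.32 and 0.35 on the deposited scale. Without arrays 5 and 6 of both groups, CHLM gave 0.0929 and PRPS10 -0.38. Without 1 array or pair the ranges were -0.18 to 0.21 for PRK, -0.32 to 0.28 for PRXIIE, -0.41 to 0.0726 for CHLM, -0.27 to 0.60 for PRPS10 and -0.0141 to 0.80 for PRPL5. For these sign changes the cause was not tested. No depth or signal over background is known for dim features.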

Other observations

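A further pair of gene groups was put together from gene symbols after the data were examined, and none of their members passed the threshold. The first held 5 measured genes tied to the plastid NDH complex, which serves cyclic electron flow around photosystem I. Among them, NdhS had an intensity of 9.8 ± 1.47 in red and 9.17 ± 3.12 in white light (SD, n = 3). CRR21 had 0.398 ± 0.0656 and 0.354 ± 0.00985, and PIFI 0.409 ± 0.145 and 0.585 ± 0.0642. NdhN was listed at 0 on 3 white and 5 red arrays and CRR41 on 4 white and 6 red arrays. The list did not stand apart (camera p = 0.545, and p = 0.57 with an estimated correlation).

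Of 4 GH9B genes, members of glycosyl hydrolase family 9, GH9B11 had 0.426 ± 0.228 in red and 0.827 ± 0.395 in white light, and GH9B12 0.252 ± 0.0733 and 1.19 ± 1.02 (SD, n = 3). GH9B8 was at 0 on 1 white and 4 red arrays. GH9B16 had 0.366 ± 0.131 and 0.0903 ± 0.0784 (SD, n = 3), the opposite direction, with a log2 difference of 1.70 ± 0.62 (SE) and an adjusted p of 0.347. The camera p of the list was 0.496, and p = 0.602 with an estimated correlation.

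The tests of overall brightness, of shared numbers and of rotated deviations below were chosen only after the results were seen. The other splits and the simulation were set out before they were run, but after the counts they concern were known. With 10 splits of the 6 pair means, no share under 0.05 can be reached. The real split gave 4 features and the highest other split 1, so 1 of 10 splits gave as many. For the unadjusted count the real split gave 475 and the highest other 396, and for the fit of 12 arrays 564 against 458, each reached by 1 of 10 splits. The split with 396 and 458 features set white pairs 1 and 2 with red pair 2 against the rest. Like every other split it keeps part of the light contrast, and it also sets pair number 2 against number 3. Among the 4 splits that keep 1 sample of each number on either side, the highest other counts were 0, 174 and 86. With these 4 splits, too, no share under 0.05 can be reached.

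The first pattern is the gap between 564 calls from 12 arrays and 4 from pair means. Arrays simulated with no light effect, but with the measured spread between and within pairs, gave a median of 119.5 and at most 171 calls in the 12-array fit, and 0 of 100 simulations reached 564. For the pair means, the simulations gave a median of 0 and at most 1 call, and 0 of 100 reached 4. This met the prediction written against near-duplicates as the cause of the 564. That prediction took features as independent, and features that vary together make such counts swing more widely. When the measured deviations of the pair means were rotated at random, which removes the light effect and keeps the correlation between features, the 12-array count had a median of 46 and a maximum of 1086. It reached 564 in 53 of 500 rotations (10.6%). The unadjusted count reached 475 in 54 rotations (10.8%), and the pair-mean count reached 4 in 13 (2.6%). These rotations and the simulation ignore the pairing by number, so the number effect is part of their spread. When only the 3 red minus white differences were rotated and the means of each number were kept, the 12-array count had a median of 0 and a maximum of 586. It reached 564 in 4 of 500 rotations (0.8%), the unadjusted count reached 475 in 21 (4.2%), and the pair-mean count reached 4 in 9 (1.8%). With the pairing, the 0.8% met the prediction, written after the results were seen, against near-duplicates as the cause of the 564. It cannot decide the question, because it rests on 2 residual degrees of freedom. It also rests on a pairing that was read from the same deviations and that the labels do not state. Without the pairing, near-duplicates counted as independent cannot be told apart from an effect of light. How many of the 564 come from the light stays open.

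The second pattern is the lopsided result on the deposited scale, where 23 of 27 calls and 82% of features at an unadjusted p under 0.05 were higher in red. The median log2 difference over all features on that scale was 0.54 in pair 1, 0.29 in pair 2 and -0.01 in pair 3. After scaling to the same median, 49.3% of features at an unadjusted p under 0.05 were higher in red. In 20 simulations, 316 features were raised by a log2 of 1 or 2 in data with no other difference. On average 64% and 67.8% were then higher after this scaling, with lowest values of 59.3% and 63.8%. The observed 49.3% lay below these, but the simulations took features as independent. The share does not decide on a difference in overall brightness, because the scaling would also remove a rise shared by most features. The highest deposited value was 85.0, 78.5, 74.1 and 87.5 on white arrays 1 to 4 and 100 on red arrays 1 to 4. These values argue against scaling of those white arrays to their own brightest deposited feature. Scaling to a spot without a deposited value, more labelled RNA in red light and a rise of most transcripts stay open.

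The third pattern is that arrays with the same number deviate from their group means together. The mean residual correlation was 0.322 for same-numbered pair means and at most 0.133 for the other 5 matchings. With 6 matchings the share cannot fall under 0.05. Handling or membranes shared by same-numbered arrays may explain this, as may plants grown side by side. Between single arrays of the 2 groups, the correlation was 0.171 to 0.409 for exactly the same number. It was 0.0275 to 0.342 for the number of the near-duplicate, and lower within each pair number. Plants alone would not give this excess if near-duplicates came from the same plants. The labels do not state that and name no batch, so the 2 cannot be told apart.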
